A study of Arabidopsis with 6 samples.

How the data were processed

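RNA from leaves of 3-week-old Arabidopsis thaliana plants was sequenced 24 h after dip inoculation with the bacterial leaf pathogen Pseudomonas syringae pv. tomato DC3000 (Pst DC3000) at an OD600 of 0.1. Wild type Col-0 and the mutant eij1-1 gave 3 libraries each, and plants were grown at 22 °C with 12 h of light and 12 h of darkness, per the labels' protocols. The tissue label gives leaves, whereas the extraction text speaks of seeds. Samples without bacteria were not analysed here, so every comparison is between inoculated genotypes. The labels do not say whether the libraries of a genotype came from separate plants or growths. The p-values of the genotype comparison therefore measure only the spread between these libraries, which may be technical.

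The table holds 923 genes, chosen by the authors. In the authors' deposited table every false discovery rate (an adjusted p-value) was under 0.01 and every absolute log2 fold change was over 1. The lowest total count of a listed gene was 200. The deposited columns give raw read counts per gene and library, FPKM per gene and library, the authors' adjusted p-value and the authors' log2 fold change, per the file headers. The submitters' processing notes name Bowtie2 2.2.3, TopHat2 2.0.12, HTSeq 0.6.1, DESeq 1.18.0 and the genome build TAIR10, without their roles, so strand handling and the treatment of reads matching several genes are not given in the sources used here. Gene names came from the deposited table and from a RefSeq gene table of assembly TAIR10.1, in which 922 of the 923 loci were found. Its coordinates served only to find neighbouring and overlapping genes.

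The summed counts of the listed genes are not library depths, and the depth of the whole libraries is unknown here. The size factors behind the authors' log2 fold changes were recovered from the counts and those fold changes over 897 genes, with a largest residual of 5.3e-10 in log2. They were 0.9272, 1.06 and 0.7146 for wild type replicates 1 to 3 and 0.9715, 1.1416 and 1.284 for eij1-1 replicates 1 to 3. Normalised read counts are raw counts divided by these factors. Relative depth implied by the ratio of counts to the authors' FPKM served as an alternative scaling.

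Genotypes were compared with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3, robust fit) on the deposited counts, with genotype as the only term and Benjamini-Hochberg adjustment over the 923 listed genes at 0.05. The plan fixed before the data were examined was TMM scaling with edgeR's expression filter. TMM assumes that most genes are unchanged, and the table holds only genes selected as changed, so TMM over it centres the fold changes near 0. The recovered factors replaced it after the table was seen, and the result with TMM is given beside the main count. The expression filter was run with library sizes built from the listed genes, since library depth is unknown, and it removed no gene. Because every gene was listed for having differed between these same libraries, a test of it here is not independent evidence, and false discovery rates over the listed genes are too favourable. Genes outside the table have no value here, and no enrichment against a genomic background was computed.

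The 23 gene lists, holding 366 loci, were fixed before the data were examined: 17 functional lists with 309 loci and 6 lists of markers of other organs and cell types with 57 loci. Lists with at least 5 listed members were tested with camera (limma 3.58.1, preset inter-gene correlation, two-sided), which compares a list with the other listed genes, and with fry. The genes named were, by a rule fixed before the data were examined, the 6 with the largest positive and the 6 with the largest negative log2 fold change among called genes with non-overlapping libraries, up to 2 members of each list in each direction, and PR1, PR2, PR5, ICS1, EDS1, PAD4, SAG101, FMO1, FRK1, PDF1.2A and VSP2. A mean of 50 normalised counts stood in for the planned minimum in CPM. Other list members are named to complete a list's count and were chosen after their values were seen. The locus of EIJ1 was not established from the names used here.

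The comparison was tested on simulated counts for the 923 genes, 200 of them changed. It recovered 100% of the genes changed by 1 log2 unit and 100% of those changed by 2, and called 1% of the unchanged genes. The simulation gave every gene the same spread, took the recovered factors as exact and left most genes unchanged. The real genes differ in spread and were selected as changed, so these shares do not describe the real calls. The common biological coefficient of variation in the real counts was 0.134. Replicates of a genotype differed by more than counting noise, with a median chi-square between 2.9 and 3.44 times that noise, so no library was treated as a duplicate. Where all 3 wild type libraries held 0 counts, a lower bound of the fold was set against 3 counts over the 3 libraries. Ratios with 1 to 3 wild type counts carry exact 95% binomial intervals. Floors and intervals cover counting error only. Standard errors of log2 fold changes were derived from the edgeR F statistic.

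Alternatives were TMM and median-of-ratios scaling over the listed genes, FPKM-implied depth, no filter, a mean count of at least 50, DESeq2 1.42.0, limma-voom, a replicate block, leaving out each library, a stricter threshold and a minimum fold. DESeq2 with the recovered factors and an adjustment bounded over all 38094 genes of the RefSeq table were added after the data were seen. Gene families were set by annotated protein domain or name after the values were seen, and were redefined once after their first tests because a narrower name match had missed members. Fisher's exact tests, two-sided, and permutations used scipy 1.17.1, with pandas 2.3.3, and figures used matplotlib 3.10.9. The Fisher's exact tests and permutations take genes as units and measure no spread between libraries. They treat genes that change together as independent, so their p-values are too favourable.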

Results

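The transcriptomes of wild type Col-0 and eij1-1 leaves were compared 24 h after dip inoculation with Pst DC3000, a bacterial pathogen of Arabidopsis leaves. EIJ1 is known as a J-domain protein that interacts with EDS1, a central regulator of immunity. There were 3 libraries per genotype. The deposited table covered 923 genes that the authors had selected as different between the genotypes, and other genes were not analysed here. Counts over these genes summed to 1275586, 1449090 and 1003861 in wild type replicates 1 to 3, and to 2207844, 2600449 and 2899029 in eij1-1 replicates 1 to 3. These sums follow the selection and are not sequencing depths. Values below are normalised read counts, as mean ± SD with n = 3 per genotype, and log2 fold changes are eij1-1 minus wild type ± SE.

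The comparison asks which transcripts differ between eij1-1 and wild type in infected leaves. In the authors' deposited table, 667 genes were higher in eij1-1 and 256 were lower. The median change was 3.16-fold among the higher genes and 2.46-fold among the lower genes. By the authors' deposited table's fold changes, 246 genes were over 4-fold higher and 36 over 4-fold lower, and 60 were over 16-fold higher and 3 over 16-fold lower. Among the fixed lists, members for salicylic acid, pattern-triggered immunity and camalexin were mostly on the higher side, and the few listed members for jasmonate, light harvesting and abscisic acid mostly on the lower side. Broader annotation terms for these processes were looked up after the values were seen and tested for direction against the other listed genes, and those for hormones were mixed. edgeR's quasi-likelihood test, adjusted over the listed genes, called 664 higher and 250 lower, or 72.6% higher. With TMM scaling over the listed genes, which moves the median log2 fold change by -1.32, the split was 339 higher and 324 lower, or 51.1% higher. The ranking of sizes turned with it, from a median log2 fold change of 1.66 in the genes listed as higher and -1.3 in those listed as lower to 0.34 and -2.62. Under TMM 91 genes were over 4-fold higher and 256 over 4-fold lower, and 19 were over 16-fold higher and 8 over 16-fold lower. Of the genes listed as higher 212 turned negative, and of those listed as lower 0 turned positive. TMM moves all listed genes downward by about the same amount, so a gene stays positive only where its log2 fold change exceeds that shift. With every absolute log2 fold change over 1, the shift fixes in advance that genes listed as lower stay negative and pass 4-fold. Signs under TMM, here and below, thus reflect the size of a change and are no independent check of its direction. Library values did not overlap between genotypes in any of the 923 genes, where chance gives 10%, but the genes had been selected on this difference.

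Several transcripts were near the detection floor in wild type. The receptor-like kinase gene AT1G51830 had 0 counts in all 3 wild type libraries and 225 ± 11 in eij1-1, at least 202-fold higher. It lies among neighbouring kinase genes alike in sequence, so its single value is uncertain. HAK5, a high-affinity potassium transporter gene, had 0 counts in wild type and 200 ± 38 in eij1-1, at least 181-fold higher. The bounds were 164-fold for AT2G11405, 117-fold for AT2G43740 and 89.6-fold for AT1G33910. Bounds are 1.52 times smaller without wild type replicate 1 and 1.65 times smaller without wild type replicate 2, since the same 3 counts then stand over fewer libraries. CYP71B14 (AT5G25180), a cytochrome P450 gene, had 3 counts in wild type and 928 in eij1-1, a ratio of 246 with a 95% interval of 83.9 to 1195. All 3 counts lay in wild type replicate 1, and without that library CYP71B14 was at least 162-fold higher. Without wild type replicate 2 the ratio was 149, with an interval of 51 to 726. On the lower side, MRD1 (AT1G53480) had 1911 ± 101 in wild type and 45.4 ± 13.9 in eij1-1, 42.1-fold lower (log2 -5.39 ± 0.15, edgeR adjusted p = 2.5e-10). AT2G33680 was 34.3-fold lower and AT1G54020 was 23.7-fold lower, and single libraries weigh on both sizes. The log2 fold change of AT2G33680 went from -5.22 to -7.3 without eij1-1 replicate 1, and that of AT1G54020 from -4.43 to -5.04 without eij1-1 replicate 3. VSP1 was 12.3-fold lower, the cold-response regulator gene CBF1 (AT4G25490) 9.78-fold lower and the methyltransferase gene IGMT5 (AT1G76790) 7.26-fold lower.

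The EIJ1 transcript itself could not be checked against the genotype labels, because its locus was not established here. Of the listed genes, 5 carry a DnaJ annotation, and they were looked up after the values were seen. AT2G24860 was lower in eij1-1, at 476 ± 77 against 2482 ± 46.4 (log2 -2.39 ± 0.10, edgeR adjusted p = 1.3e-09), and AT5G53150 was lower at 195 ± 97.9 against 472 ± 10.8 (edgeR adjusted p = 0.018). AT5G53150 lost its call without wild type replicate 1, 2 or 3 or without eij1-1 replicate 2, with edgeR adjusted p from 0.061 to 0.077. AT1G44160, AT3G13310 and AT1G72416 were higher, though AT1G72416 had a log2 fold change of only 1.01, which is under the shift that TMM makes. Which of these, if any, is EIJ1 is left open.

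Genes for making and modifying salicylic acid and the related signal N-hydroxypipecolic acid were higher in eij1-1. Of the 14 loci in this list 7 were listed, and 7 were higher, 5 of them also in sign under TMM. ICS1 (AT1G74710), which makes the isochorismate precursor of salicylic acid, went from 2503 ± 99 in wild type to 8578 ± 53 in eij1-1 (log2 1.78 ± 0.04, edgeR adjusted p = 2.4e-12). ALD1 (AT2G13810) and FMO1 (AT1G19250), enzymes of the N-hydroxypipecolic acid pathway, were 13.5-fold and 3.06-fold higher, with ALD1 at 61.8 ± 5.79 in wild type and 834 ± 97.8 in eij1-1. PBS3, which conjugates isochorismate to glutamate, was 5.41-fold higher, and UGT76B1, a glucosyltransferase acting on these signals, was 7.27-fold higher. EDS5, the isochorismate exporter of the plastid, was 2.19-fold higher and SARD4 was 2.48-fold higher. Adjusted over the list alone, 7 were called, which the selection makes near certain. The list was not past the threshold against the other listed genes (camera adjusted p = 0.12). The annotation term for salicylic acid biosynthesis, looked up after the values were seen, held 34 higher and 2 lower genes (Fisher's exact adjusted p = 0.009 over 144 terms), with 18 positive and 18 negative under TMM.

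In the list of salicylic acid response and systemic resistance markers 8 of 22 loci were listed and 8 were higher, 6 of them also in sign under TMM. Broader annotation terms differed in direction. Response to salicylic acid had more genes lower, with 8 higher and 12 lower (Fisher's exact adjusted p = 0.028; 4 positive and 16 negative under TMM). Systemic acquired resistance held 31 higher and 1 lower (Fisher's exact adjusted p = 0.0057; 18 and 14 under TMM). Its salicylic acid mediated pathway held 38 higher and 6 lower (adjusted p = 0.12; 26 and 18 under TMM), and salicylic acid mediated signalling 17 higher and 2 lower (adjusted p = 0.27; 13 and 6 under TMM). PR1 (AT2G14610), the widely used marker of salicylic acid responses, rose from 9635 ± 764 in wild type to 26936 ± 940 in eij1-1, 2.8-fold (log2 1.48 ± 0.06, edgeR adjusted p = 2.5e-08). NIMIN1, whose protein binds the salicylic acid receptor NPR1, was 10.4-fold higher at 386 ± 52 against 37 ± 10.8. AIG1 was 3.57-fold higher, LURP1 2.84-fold, NIMIN2 3.04-fold and WRKY62 2.99-fold. WRKY54 and MLO2 were 2.14-fold and 2.07-fold higher. The call count adjusted over the list alone was 8, and camera gave an adjusted p = 0.13. PR2 and PR5 were not analysed here.

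Of the EDS1 node and the NLR receptors, intracellular immune receptors, 1 of 19 loci was listed. This was EDS1B (AT3G48080), a close copy of EDS1, at 822 ± 41.4 in wild type and 1825 ± 103 in eij1-1 (log2 1.15 ± 0.06, edgeR adjusted p = 7.4e-09). Its sign turned under scalings computed over the listed genes, which centre selected genes near 0, with a log2 fold change of -0.17 under TMM. The sign held with FPKM-implied depth. Reads shared with EDS1 leave the value of EDS1B uncertain. It was the 1 gene called when adjusted over the list alone. EDS1, PAD4 and SAG101 were not analysed here.

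**Figure D1:**
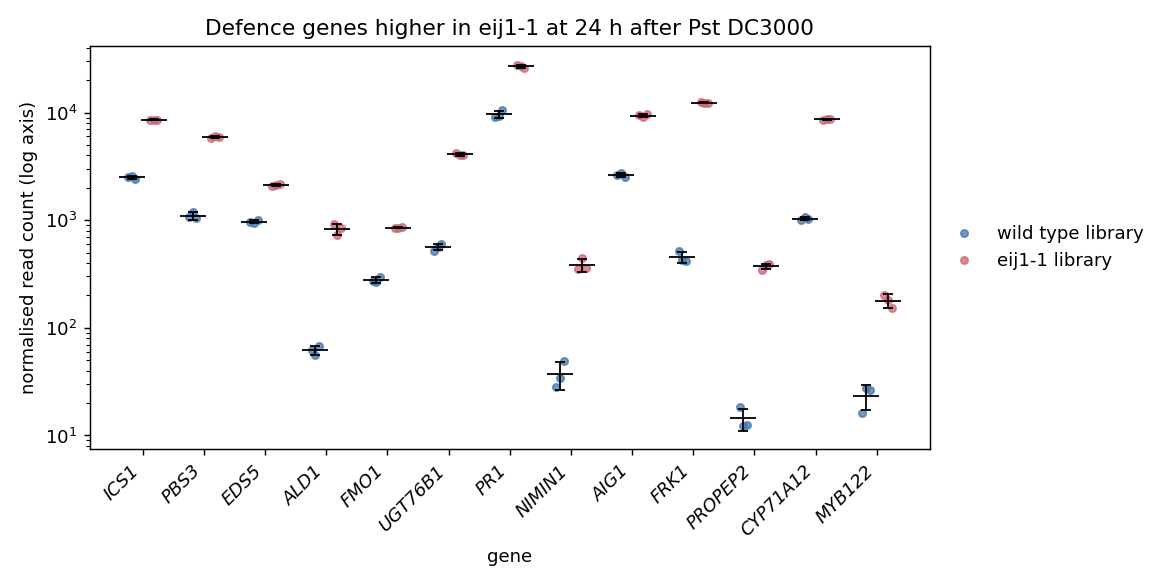
Normalised read counts on a log axis for 13 defence genes, in wild type (blue) and eij1-1 (red) leaves. Points are the 3 libraries of each genotype, and black marks are the mean with SD. Every eij1-1 library lies above every wild type library for each gene, from 455 to 12367 on average for FRK1 and from 9635 to 26936 for PR1. Under TMM scaling over the listed genes, EDS5 changes sign.

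Pattern-triggered immunity genes, which respond to microbial molecules sensed at the cell surface, held some of the larger changes. Of 24 loci 7 were listed, 6 higher and 1 lower, and under TMM 5 were positive and 2 negative. FRK1 (AT2G19190), a receptor-like kinase gene induced by flagellin, was 27.2-fold higher at 12367 ± 200 in eij1-1 against 455 ± 53.6 in wild type (log2 4.76 ± 0.08, edgeR adjusted p = 1.8e-11). PROPEP2, the precursor of an immune peptide, was 25.9-fold higher at 373 ± 23.1 against 14.4 ± 3.41. PROPEP3 was 3.87-fold higher, WRKY29 3.84-fold, NHL10 3.38-fold and WRKY22 2.2-fold. PHI-1 (AT1G35140) went the other way, 3.08-fold lower. The count adjusted over the list alone was 7, and camera gave an adjusted p = 0.37. Among annotation terms, defence response to bacterium held 42 higher and 3 lower genes (Fisher's exact adjusted p = 0.0057; 29 and 16 under TMM). Response to molecules of bacterial origin held 13 higher and 1 lower (adjusted p = 0.28; 6 and 8 under TMM), and response to chitin 64 higher and 38 lower (adjusted p = 0.11; 40 and 62 under TMM). Response to bacterium, at 12 higher and 4 lower (adjusted p = 1; 7 and 9 under TMM), was not past the threshold. Response to fungus was on the lower side with 5 higher and 9 lower (adjusted p = 0.032; 3 and 11 under TMM), while defence response to fungus held 59 higher and 11 lower (adjusted p = 0.082; 41 and 29 under TMM).

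For camalexin, the main antimicrobial indole compound of Arabidopsis, and the indole glucosinolates, 4 of 16 loci were listed and 4 were higher, with 4 called when adjusted over the list alone. CYP71A12 (AT2G30750), which converts indole-3-acetaldoxime, was 8.37-fold higher at 8653 ± 64.9 against 1034 ± 27.2 (edgeR adjusted p = 7.8e-14). MYB122, a regulator of indole glucosinolate genes, was 7.66-fold higher at 179 ± 25.2 against 23.4 ± 6.24. The glutathione transferase gene GSTF6 was 2.03-fold higher and the tryptophan synthase gene AT3G54640 was 2.39-fold higher, and under TMM 2 of the 4 were negative. Outside the list, IGMT5, which methylates indole glucosinolates, was lower at 21.5 ± 9.55 against 156 ± 9.68. The annotation term for glucosinolate biosynthesis held 4 higher and 6 lower genes (Fisher's exact adjusted p = 0.11).

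Of the jasmonate lists, 8 of 9 listed members were lower in eij1-1. In the MYC2 branch, which responds to wounding and insects, 6 of 18 loci were listed, 5 lower and 1 higher, and the higher member stayed positive under TMM. VSP1 (AT5G24780) and VSP2 (AT5G24770), wound-responsive storage protein genes, fell from 326 ± 16.7 to 26.4 ± 0.772 and from 218 ± 13.7 to 46.2 ± 6.84. The regulator MYC2 was 2.35-fold lower, the repressor gene JAZ8 2.53-fold lower and CLH1 2.03-fold lower. NAC055 was 3.03-fold higher at 775 ± 66.3 against 256 ± 9.59. The branch was lower than the other listed genes (camera adjusted p = 0.0095), though not past the threshold with a correlation estimated from the data (adjusted p = 0.17 with an estimated correlation). The 6 members were also called when adjusted over the list alone. None of the other lists tested was past the camera threshold with either correlation.

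In the jasmonate and ethylene branch 2 of 7 loci were listed and 2 were lower. PDF1.2A (AT5G44420), a plant defensin gene, was 3.41-fold lower at 1377 ± 67.3 against 4696 ± 173 (log2 -1.77 ± 0.05, edgeR adjusted p = 2.5e-11). PDF1.2C was 5.27-fold lower, and the near-identical copies of this defensin leave the split of reads between them uncertain. Of 16 jasmonate biosynthesis and turnover loci 1 was listed, LOX2 (AT3G45140), a plastid lipoxygenase of jasmonate synthesis, which was 2.2-fold lower at 16624 ± 194 against 36547 ± 452. Calls adjusted over the list alone were 2 and 1. Annotation terms for jasmonate did not share a direction. Response to jasmonic acid held 12 higher and 17 lower genes (Fisher's exact adjusted p = 0.0057; 8 and 21 under TMM), and jasmonic acid biosynthesis held 8 higher and 11 lower (adjusted p = 0.041; 6 and 13 under TMM). Jasmonic acid mediated signalling held 35 higher and 8 lower (Fisher's exact adjusted p = 0.37; 22 and 21 under TMM). Terms for ethylene also differed, with 6 higher and 19 lower for ethylene-activated signalling (adjusted p = 2.4e-05; 2 and 23 under TMM) and 25 higher and 4 lower for response to ethylene (adjusted p = 0.24; 19 and 10 under TMM). Ethylene biosynthesis held 8 higher and 10 lower (adjusted p = 0.069; 8 and 10 under TMM).

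In the abscisic acid list 4 of 22 loci were listed, 3 lower and 1 higher. NCED3, which catalyses a rate-limiting step of abscisic acid synthesis, was 3.48-fold lower. CYP707A3 and CYP707A1, which break abscisic acid down, were 5.59-fold and 2.62-fold lower, with CYP707A3 at 435 ± 16.3 in eij1-1 and 2430 ± 69.3 in wild type. COR15A was 2.07-fold higher (log2 1.05 ± 0.15, edgeR adjusted p = 5.3e-05), and its log2 fold change was -0.27 under TMM. Adjusted over the list alone, 4 were called. The annotation term for response to abscisic acid held 18 higher and 15 lower genes (Fisher's exact adjusted p = 0.11; 12 and 21 under TMM), and abscisic acid-activated signalling held 24 higher and 11 lower (adjusted p = 0.86; 17 and 18 under TMM).

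**Figure D2:**
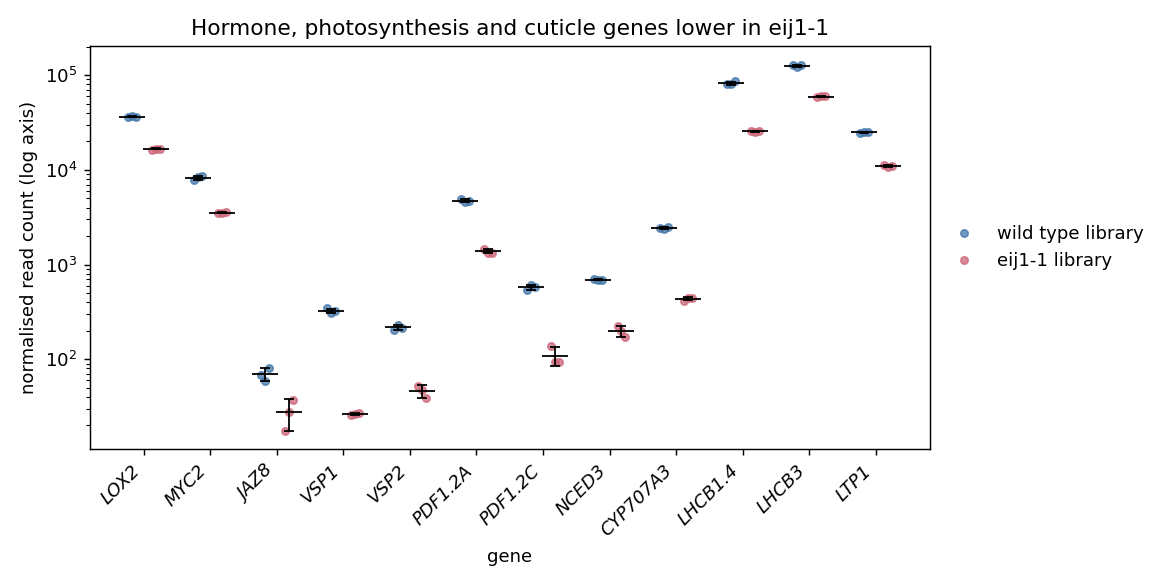
Normalised read counts on a log axis for 12 genes lower in eij1-1 (red) than in wild type (blue). Points are the 3 libraries of each genotype, and black marks are the mean with SD. The 3 libraries of each genotype lie apart for every gene, for example at 36547 and 16624 on average for LOX2.

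Nuclear photosynthesis genes were listed for 3 of 44 loci, all light-harvesting antenna genes and all lower. LHCB1.4 was 3.22-fold lower, LHCB3 2.13-fold lower, from 126150 ± 2955 to 59186 ± 799, and LHCB1.1 2.01-fold lower. The LHCB1 copies are alike in sequence, so their individual values are uncertain. Leaf senescence genes were listed for 6 of 16 loci, and 6 were higher, 4 of them also in sign under TMM (camera adjusted p = 0.15). ORE1 (AT5G39610), a NAC regulator of senescence, was 8.17-fold higher at 1261 ± 59.6 against 154 ± 3.9, and NYE2, which acts in chlorophyll breakdown, was 3.99-fold higher. SEN1, XTH24, SAUR36 and NAP were 2.83-fold, 2.59-fold, 2.19-fold and 2.14-fold higher. Calls adjusted over the list alone were 3 and 6. The annotation term for leaf senescence held 12 higher and 4 lower genes (Fisher's exact adjusted p = 1; 8 and 8 under TMM).

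Auxin response genes were listed for 3 of 9 loci and 3 were higher, with 1 positive and 2 negative under TMM. GH3.3, an enzyme that joins auxin to amino acids, was 6.92-fold higher at 726 ± 23 against 105 ± 9.67. GH3.5 was 2.13-fold higher and GH3.6 2.43-fold higher, the latter with a log2 fold change of -0.03 under TMM. The annotation term for response to auxin held 20 higher and 14 lower genes (Fisher's exact adjusted p = 0.21; 15 and 19 under TMM). Of 15 oxidative stress loci 2 were listed, with the zinc finger gene ZAT10 2.12-fold lower and the glutathione transferase gene GSTU24 2.75-fold higher. GSTU24 lost its call under TMM (log2 0.15), and it has close copies. The list alone gave 3 and 2 calls. Response to oxidative stress, the annotation term, held 21 higher and 6 lower genes (Fisher's exact adjusted p = 0.82; 13 and 14 under TMM). None of the 20 heat shock, 19 endoplasmic reticulum folding, 16 circadian clock and 12 flavonoid loci was among the listed genes. The annotation terms held other genes, with 23 higher and 1 lower for response to endoplasmic reticulum stress (Fisher's exact adjusted p = 0.034; 12 and 12 under TMM) and 5 higher and 8 lower for response to heat (adjusted p = 0.054; 2 and 11 under TMM).

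Across the 17 functional lists 54 of 309 loci were listed, 38 higher and 16 lower. Among markers of other organs and cell types 1 of 57 was listed, the epidermal gene LTP1 (AT2G38540), which encodes a lipid transfer protein, at 11021 ± 241 in eij1-1 against 24897 ± 424 in wild type. It was 1 of 6 epidermis markers and was called when adjusted over the list alone. No marker was listed among 13 for seed, 10 for root, 9 for flower and shoot apex, 6 for guard and myrosin cells and 13 for vasculature.

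In 9 listed genes the edgeR test did not call a difference, with adjusted p from 0.058 to 0.3. PCC1 (AT3G22231), a gene known from pathogen and clock responses, was at 2174.4, 15.1 and 278.5 in the wild type libraries and 7378 ± 1249 in eij1-1 (edgeR adjusted p = 0.12). POT8 (AT5G14880), a potassium transporter gene, was at 2808 ± 157 in wild type and at 227.5, 5.3 and 1112.1 in the eij1-1 libraries (edgeR adjusted p = 0.13). The other genes were AT1G75460, GLR1.4, HSP70-3 (AT3G09440), ATA20, AT3G17611, AT3G62720 and AT4G14368. Of the 9 genes, 7 spread over 4-fold among the libraries of a genotype. All 9 were called when a certain library was left out. PCC1 was called without wild type replicate 1 (log2 5.72 against 3.16, edgeR adjusted p = 0.027), HSP70-3 without wild type replicate 2 (0.62 against 1.1) and AT4G14368 without wild type replicate 3 (6.38 against 2.01). AT1G75460 (log2 -5.34 against -1.95), GLR1.4 (-4.75 against -2.4), AT3G17611 (-1.62 against -1.08) and AT3G62720 (-0.89 against -1.28) were called without eij1-1 replicate 1. ATA20 was called without eij1-1 replicate 2 (log2 -8.73 against -2.91) and POT8 without eij1-1 replicate 3 (-4.64 against -2.63).

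**Figure D3:**
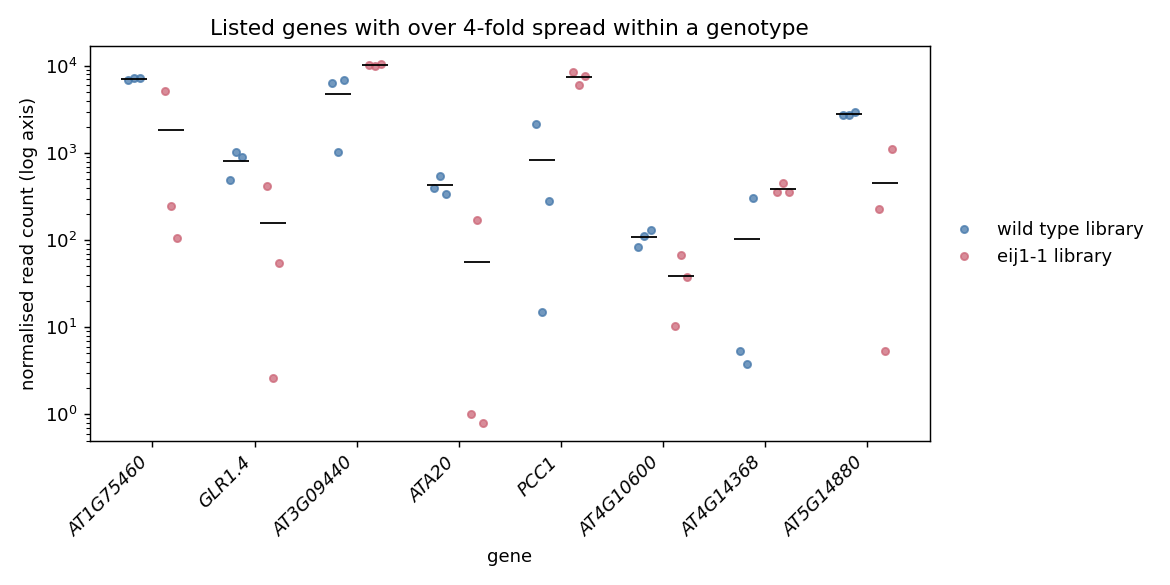
Normalised read counts on a log axis for the 8 listed genes that spread over 4-fold among the 3 libraries of a genotype, in wild type (blue) and eij1-1 (red). AT3G09440 is HSP70-3 and AT5G14880 is POT8. Points are libraries and black marks are means, without error bars. The wide group holds values from 15.1 to 2174.4 for PCC1 in wild type and from 5.3 to 1112.1 for POT8 in eij1-1.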

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

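The alternatives were chosen before the data were examined, except for the 2 named as added and the switch of the main scaling from TMM to the recovered factors. Scaling factors computed over the listed genes decided most of what moved, because they centre genes that were selected as changed. With TMM, median-of-ratios factors in edgeR and DESeq2 with its own factors, genes higher in eij1-1 numbered 339, 344 and 339 against 664, and genes lower 324, 316 and 316 against 250. Under each of these settings members called higher numbered 5 for salicylic acid response, 0 for the EDS1 node and NLR receptors, 2 for camalexin and indole glucosinolates, 0 for abscisic acid, 2 for senescence, 0 for oxidative stress and 1 for auxin response, and members called lower numbered 2 for pattern-triggered immunity. In the same order of settings the log2 fold changes changed sign to -0.17, -0.15 and -0.15 for EDS1B, to -0.27, -0.25 and -0.25 for COR15A and to -0.03, -0.01 and -0.01 for GH3.6. GSTU24 lost its call at 0.15, 0.16 and 0.16. Library totals are unknown, so FPKM-implied depth stood in for them, and the CPM part of the stricter filter was not run. FPKM-implied depth, limma-voom, a threshold of 0.01, a minimum absolute log2 fold change of 1 and leaving out any library left the counts of calls within 1.5 times, with 661 to 665 higher and 248 to 254 lower when a library was left out. Leaving out a library changed no call of a set test or of a gene named by the fixed rule. AT5G53150 lost its call, and the 9 genes not called each gained 1, when a certain library was left out. Listed genes outside the named genes, the lists and the DnaJ genes were not followed singly. Some of them lost calls too, as genes called higher went from 664 to 661 without eij1-1 replicate 3. Among the set tests, fry passed the threshold where camera did not, with adjusted p of 8.7e-07 for salicylic acid biosynthesis, 2.8e-06 for salicylic acid response, 4.6e-06 for pattern-triggered immunity and 3.9e-06 for senescence. fry asks only whether members move to a side on balance, which selected genes do. The jasmonate MYC2 branch had an adjusted p = 0.17 with an estimated correlation. A mean count of at least 50 left 882 genes, with 637 higher and 236 lower. Added after the data were seen, DESeq2 with the recovered factors gave 664 and 252, and an adjustment bounded over all genes of the RefSeq table gave 650 and 239. Replicate numbers did not pair the libraries, with correlations of deviations of 0.02, -0.01 and 0.05, and the replicate block gave 661 higher and 251 lower. Running without a filter kept the same 923 genes and so tests nothing. Removing organelle genes was not run, since 0 organelle loci were listed, and the alternatives for other kinds of values did not apply. Sequencing depth is unknown, and genes outside the table have no value here.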

Other observations

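All tests in this part, and the definitions of the gene families from domain and protein annotations, were chosen after the results were seen, and each runs on genes already selected as different. Families were compared in direction with the other listed genes, by 2-sided Fisher's exact tests adjusted over 9 families. The 16 listed WRKY genes were all higher in eij1-1 (adjusted p = 0.026), though 4 were negative under TMM. WRKY61 went from a mean of 6.87 to 247 normalised counts and WRKY75 from 321 to 1384. ERF and DREB genes, which include ethylene and cold regulators, were 3 higher and 21 lower (adjusted p = 8.4e-09), and the 3 higher ones stayed positive under TMM. CBF2 went from 669 to 116, RRTF1 from 189 to 39.1 and ORA47 from 1065 to 278, while RAP2.6 went from 21.9 to 122. MYB genes were 6 higher and 7 lower (adjusted p = 0.12; 5 positive and 8 negative under TMM). The lower ones include MYB29 and MYB76, regulators of aliphatic glucosinolates. NAC genes were 11 higher and 1 lower (adjusted p = 0.28; 7 and 5 under TMM).

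Receptor-like kinases were 45 higher and 2 lower (adjusted p = 0.00018), but 26 positive and 21 negative under TMM. Between AT1G51790 and AT1G51890, 7 of 7 listed genes were higher, including IOS1, from 2577 to 13362. These neighbours are alike in sequence, so their single values are uncertain. Of 83 pairs of adjacent listed genes 76 had the same direction, against a median of 50 in 10000 permutations of direction (one-sided permutation p = 0.0001, the smallest they can give). Class III peroxidases, cell wall and peroxide enzymes, were 13 higher and 2 lower (adjusted p = 0.29; 10 and 5 under TMM), with AT5G64120 from 7768 to 67497 and AT5G64100 from 63 to 3119. UDP-glycosyltransferases were 10 higher and 0 lower (adjusted p = 0.13; 10 positive under TMM). Cytochrome P450 genes were 12 higher and 8 lower (adjusted p = 0.28; 10 and 10 under TMM), and glutamate receptors 4 and 1 (adjusted p = 1), as under TMM.

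More listed genes were higher than lower in eij1-1, 667 against 256 in the authors' deposited table. The authors' scaling factors could have made this asymmetry if they stood far from library depth. FPKM-implied depth moved the scaling between the genotypes by 0.105 in log2, toward eij1-1 higher, which argues against that. Both scalings were derived from the authors' deposited values, so a bias shared by both was not tested. Of the 10 splits of the 6 libraries, 1 gave as many edgeR calls, the real split with 914 and the highest other with 0. The genes were selected for differing in the real split, and 10 splits are too few for a share under 0.05. The splits therefore decide nothing here, and a number of calls does not bear on their direction. A genotype effect on immunity and a difference in bacterial growth between the genotypes stay open and were not tested.

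In 8 listed genes counts spread over 4-fold among replicates of a genotype. An aberrant library behind all 8 is argued against, since 5 spread within eij1-1 and 3 within wild type, and a library belongs to 1 genotype. An aberrant library behind all 5 genes in eij1-1 is also argued against, since no left-out library ended the spread of all 5. An aberrant library behind some of the 5 stays open. Leaving out eij1-1 replicate 1 or 2 ended the spread over 4-fold of 2 of the 5, and leaving out replicate 3 of 0. Of the 9 genes not called, 4 were called without eij1-1 replicate 1, against 1 without each other library. Overlap with another annotated gene covered 12.5% of them against 21.1% of the other listed genes (Fisher's exact p = 1), so overlap does not account for most of the 8. For POT8 a candidate explanation is that its reads were counted for its neighbour AT5G14890 in some libraries. The sum of both genes varied by 4.2% among eij1-1 libraries, against 130.6% for POT8 alone. The sum was 3666 ± 211 in wild type and 2794 ± 117 in eij1-1, 1.31-fold lower, against 6.26-fold lower for POT8 and 2.73-fold higher for AT5G14890. If reads did move between them, the differences of both single genes are not to be read as changes in transcript level. No biological explanation was tested.

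Genes annotated to mechanical stimulus were lower in eij1-1 in 15 of 16 cases (Fisher's exact adjusted p = 5.6e-06 over 144 terms, 25 of them past the threshold). Their mean log2 normalised count differed by -1.11, with an SD of 0.05 in wild type and 0.08 in eij1-1. Handling that differed between the genotypes may account for this and cannot be told apart from genotype, because each genotype forms a block of libraries. The same limit holds for the other differences between the genotypes, those of the ERF and DREB genes included. Harvest at another time of day would be expected to bring clock genes into the table, and 0 of the fixed list were listed. Their values are not analysed here, so whether they stayed unchanged cannot be told and this explanation also stays open. The effect of the mutation itself is an untested alternative. Response to wounding, also past the threshold, held 32 higher and 33 lower genes (Fisher's exact adjusted p = 0.0013, 18 and 47 under TMM). Amino acid transport held 40 higher and 0 lower (Fisher's exact adjusted p = 7.8e-05, 34 and 6 under TMM). Nitrate transport held 52 and 4 (Fisher's exact adjusted p = 0.0025, 42 and 14 under TMM). Response to nitrate had the same counts, so these terms may hold the same genes and are not separate results. Oligopeptide transport held 24 and 0 (Fisher's exact adjusted p = 0.0066, 20 and 4 under TMM). Terms count genes annotated to a process, which need not be transporter genes, and terms can share genes.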
